A study of Mus musculus with 3 samples.

How the data were processed

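Total RNA was extracted with a column kit and hybridised to Affymetrix MoGene-1_0-st-v1 arrays after biotin labelling, per the labels. Each of the 3 groups has 1 array, and each array was placed in its group by its title and the design text of the series. The deposited values are intensities on a linear scale, 1 per probe set, as the authors gave them in a single table. How the authors corrected the background, summarised probes and normalized the arrays is not given in the sources used here. The intensities ran from 20.9 to 26412 on the array labelled control, from 21.0 to 21362 on high doxycycline and from 20.7 to 21922 on tumor, and no value was missing. Of the 28856 probe sets, 4314 (15.0%) had identical values on all 3 arrays. Exactly equal values were held by 9970 (34.6%) on the arrays labelled tumor and high doxycycline, by 6244 (21.6%) on high doxycycline and control and by 4870 (16.9%) on tumor and control. They enter the correlations, the disagreement between probe sets, the random lists and the noise of the simulation described here. Why they are equal is not given in the sources used here.

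Genes were named through the platform annotation, in which 21789 probe sets have 1 gene symbol, 1621 have several and 5446 have none. Probe sets with several symbols or none were left out of all gene results. Of those with 1 symbol, 21698 were found by Entrez number in a RefSeq gene table of the mouse (GRCm38.p6), and 0 symbols had to be updated. This left 19938 genes. For the 999 genes with several probe sets the one with the highest mean over the 3 arrays was used. No coordinates are given, since the build behind the annotation is not given in the sources used here.

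Differences were taken between log2(intensity + 1) values as deposited, so that folds are on that scale and understate changes of dim genes. A gene entered a comparison where the brighter array of the pair lay above that array's median over all probe sets. The protocadherin and Hox families of the closing section were counted without this filter. Counts take a log2 difference of at least 1 in size. For each of 28 gene lists the median difference of its bright members is given, with its percentile among 10000 random lists of the same size drawn from 10 bins of mean brightness. A list with fewer than 3 bright members has no median. The percentile describes these arrays and is not a test, and a list is said to lie inside the range of random lists between percentiles 2.5 and 97.5. The lists hold 471 entries, of which 433 were measured. The other 38 are not analysed here. They cover immediate early genes, CREB/ATF1 targets, ERK feedback, pigment cells, neural crest, Schwann cells, neuroendocrine cells, S-phase, mitosis, p53 targets, interferon, antigen presentation, hypoxia, cholesterol, ATF4, unfolded protein and heat shock responses, TGF-beta, YAP and BMP targets, matrix, smooth muscle, macrophages, lymphocytes, endothelium, red blood cells, skeletal muscle, adipocytes, keratinocytes and reference genes. Some genes stand in more than 1 list, such as Fos and Scg2.

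Named genes followed a rule. It takes Fos, Atf1 and Ewsr1, then the 8 largest increases and 8 largest decreases of each comparison without provisional, olfactory, vomeronasal, immunoglobulin and small RNA symbols, then per list up to 4 bright members that differ by at least 2-fold. Genes outside this rule were chosen after their values were seen: the remaining members where a list count is small, Entpd3, the Y-linked genes and Xist, and the protocadherin, Hox and protein complex families of the closing section. The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were a shift of all arrays to a common median, quantile normalization, no brightness filter, a filter at percentile 75, the mean of all probe sets of a gene, genes with a single probe set, and pseudocounts of 16 and 64. The shift to a common median moves all differences between the arrays labelled high doxycycline and control by 0.14, between tumor and control by 0.19 and between tumor and high doxycycline by 0.04.

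The 2 comparisons with the array labelled control share that array. To describe this, 100 simulations drew unchanged arrays against it, with noise by brightness bin taken from the arrays labelled high doxycycline and tumor (SD 0.056 to 0.283). Because these arrays differed least, 100 further simulations, chosen after seeing the data, gave the control an added error, drawn from how 2850 probe sets deviated from the mean difference of their gene between high doxycycline and control (SD 0.342 to 0.657 by brightness bin). The procedure was tested on simulated data for 1 pair of arrays with 19938 genes: with noise of SD 0.15 per array, all 100 genes changed by 1.6 and all 100 changed by 2.5 on the log2 scale were called. This checks the computation and does not measure how often the error of the real arrays passes 2-fold. Of unchanged random lists 6% fell outside percentiles 2.5 to 97.5, and 100% of lists shifted by 0.5 fell above them. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.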

Results

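Expression was measured in sarcoma cells from mice that carry an inducible EWS/ATF1 transgene. EWS/ATF1 joins the amino-terminal part of the RNA-binding protein EWSR1 to ATF1, a transcription factor of the CREB family, and is the fusion found in human clear cell sarcoma. The series holds 3 arrays, 1 per group. Per the labels, 1 array carries RNA of cultured tumor cells kept without doxycycline (0 microg/ml), 1 carries RNA of cultured cells exposed to 0.2 microg/ml doxycycline for 24 h, and 1 carries RNA taken directly from a tumor of a mouse given doxycycline for 3 months. They are called here the arrays labelled control, high doxycycline and tumor. The 28856 probe sets had median intensities of 250.0, 226.7 and 219.8 on these arrays, in that order. With 1 array per group no difference could be tested and no replicate check exists, so that all folds and counts describe these 3 arrays and carry no p-value, and the number of arrays limits the precision. The only internal measure of error was the disagreement between probe sets of the same gene. Above the array medians it had a median of 0.37 on the log2 scale for high doxycycline against control, 0.38 for tumor against control and 0.055 for tumor against high doxycycline.

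Genes of blood and vessels were bright on the array labelled control and dim on the array labelled tumor, which goes against both labels. Muscle genes, which a tumor need not hold, were also bright on control and dim on tumor. Connective tissue genes were also dimmer on tumor than on control. The median of their list was 11.05 on the log2 scale on control, 7.93 on high doxycycline and 8.10 on tumor. On tumor it lay little above the array median of 7.79. Of 19 measured collagen, matrix and fibroblast genes, 18 lay above the array median on control, 11 on high doxycycline and 13 on tumor. Of 19 measured macrophage and myeloid genes, 18 lay above the array median on the array labelled control, 2 on the array labelled high doxycycline and 1 on the array labelled tumor. Lyz2, the lysozyme of macrophages, had intensities of 3932, 68.0 and 64.8 in that order, and C1qb, a complement component made by macrophages, had 5449, 104 and 89.2. The endothelial cadherin gene Cdh5 had 2098, 135 and 106, the muscle creatine kinase gene Ckm had 4795, 238 and 210, and the type I collagen gene Col1a2 had 10078, 302 and 270. Of the 2 red blood cell genes measured, the haem synthesis enzyme gene Alas2 had 473, 130 and 114, and the anion exchanger gene Slc4a1 had 450, 208 and 177. Over all probe sets, the log2 values of the arrays labelled high doxycycline and tumor correlated at 0.991 (Pearson, across probe sets, which are not independent replicates), against 0.928 for high doxycycline and control and 0.917 for tumor and control. Identical values stood on both arrays for 34.6%, 21.6% and 16.9% of probe sets in these pairs. Every direction below is therefore one between arrays named by their labels, and is not a statement about untreated cells, treated cells or tumor tissue.

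**Figure D1:**
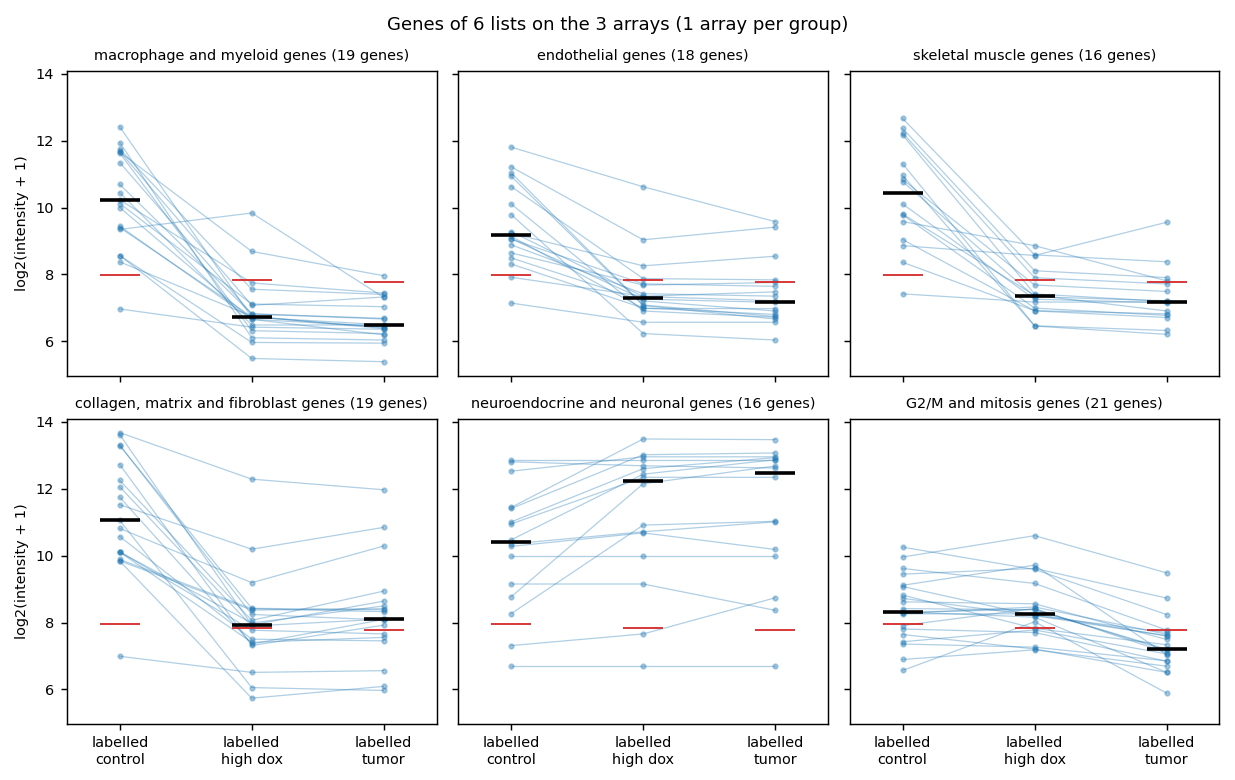
Log2(intensity + 1) of each measured gene of 6 lists (y axis) on the 3 arrays (x axis, by label); each line is 1 gene, black bars are list medians and red bars are the medians of all probe sets of the array. The median of the macrophage list was 10.23 on the array labelled control, 6.74 on high doxycycline and 6.49 on tumor, and the median of the neuroendocrine list was 10.41, 12.25 and 12.48.

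The first comparison set the array labelled high doxycycline against the array labelled control. By these labels it would ask which genes change within a day of doxycycline, which the tissue genes on the array labelled control leave unanswered. Fos, the AP-1 subunit named in the title of the series, differed little between them, with an intensity of 1234 on the array labelled high doxycycline and 1114 on the array labelled control (1.11-fold); the log2 difference of 0.15 became -0.12 under quantile normalization. Atf1 (1063 against 1189) and Ewsr1 (1650 against 1660) also lay close together. These are values of mouse probe sets, and whether they detect the transgene is not given in the sources used here. Brighter on the array labelled high doxycycline were Gabra2, a GABA receptor subunit gene (26.9-fold), Pcdhb9, a clustered protocadherin gene (25.4-fold), the cytochrome P450 gene Cyp3a44 (24.0-fold), Nell2 (19.8-fold), the neural cell adhesion gene Ncam2 (16.5-fold), Stxbp4 (15.6-fold) and Pfn2, a profilin gene (14.7-fold). Scoc was 24.5-fold brighter on its brighter probe set, but its log2 difference of 4.61 became 2.27 as a mean over its 2 probe sets. For Stxbp4, which has 2 probe sets as well, 3.96 became 2.74. Dimmer were the chemokine gene Ccl8 (82.2-fold), Wfdc17 (76.6-fold), Lyz2 (57.0-fold), the acute phase gene Saa3 (53.1-fold), C1qb (51.7-fold), the matrix gene Sparc (51.5-fold), the matrix gene Fmod (50.9-fold) and the interferon-inducible Ifi205 (43.1-fold).

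The tissue genes made up the largest list differences. All 18 bright members of the collagen, matrix and fibroblast list were at least 2-fold dimmer on the array labelled high doxycycline than on the array labelled control, with a median log2 difference of -3.58. The macrophage and myeloid list had a median of -3.21 (17 of 18 dimmer), the skeletal muscle list -3.15 (13 of 15), the endothelial list -1.87 (14 of 16) and the smooth muscle and pericyte list -1.19 (6 of 9, among them desmin, Des, 22.9-fold). The first 4 of these medians lay below every one of 10000 random lists of matched brightness, and the smooth muscle list had percentile 0.09. In the adipocyte list 2 of 4 bright genes were dimmer, Fabp4 (9.58-fold) and Lpl (3.20-fold), in the lymphocyte list 1 of 3 (Cd4, 2.44-fold), in the pigment cell list 1 of 5 (Gpnmb, 3.46-fold), and in the antigen presentation list 1 of 10, the MHC class II invariant chain gene Cd74 (39.8-fold), with a median of -0.29 (percentile 0.63).

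Some members of the neuronal, S-phase and cholesterol lists were at least 2-fold brighter on the array labelled high doxycycline, beside the tissue genes that were brighter on the array labelled control. In the neuroendocrine and neuronal list 7 of 14 genes were at least 2-fold brighter (median 0.91, percentile 98.7), among them the secretogranin gene Scg2 (10.4-fold), Uchl1 (6.26-fold) and the synaptic gene Snap25 (3.90-fold). That median lay inside the range of random lists with no brightness filter (0.42, percentile 76.5), as a mean over all probe sets of a gene (0.73, percentile 93.0) and over genes with a single probe set (0.43, percentile 61.9). In the list for cholesterol synthesis 8 of 15 genes were brighter (median 1.14, percentile 99.95), led by Idi1 (6.24-fold), Nsdhl (5.82-fold), Msmo1 (5.14-fold) and Cyp51 (4.56-fold). In the S-phase list 7 of 26 genes were brighter and none was dimmer by that margin (median 0.62, percentile 99.9), with the replication factor gene Rfc4 at 8.61-fold, the primase gene Prim1 at 4.16-fold and Pcna at 2.32-fold. Of the 16 bright G2/M and mitosis genes only Bub1 (2.74-fold) differed by at least 2-fold, and the median was -0.015, which turned positive when the arrays were shifted to a common median.

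Signalling lists moved less. Of 20 bright CREB/ATF1 target genes, Scg2, Crem (3.46-fold) and the prohormone convertase gene Pcsk1 (3.05-fold) were brighter on the array labelled high doxycycline and the clock gene Per1 (4.33-fold) was dimmer; the median of 0.12 became -0.16 under quantile normalization. Of 21 immediate early and AP-1 genes, Atf3 was brighter (2.08-fold) and Btg2 dimmer (2.29-fold), and the median of -0.49 had percentile 0.02. Among 12 TGF-beta, YAP and BMP target genes the median was -0.36 (percentile 0.12): Ltbp2 (3.81-fold), Ccn1 (3.03-fold) and Ccn2 (2.30-fold) were dimmer and Id2 (3.04-fold) was brighter. The ERK feedback list held 2 brighter genes of 12, Dusp4 (2.69-fold) and Etv1 (2.48-fold). Amino acid response genes included 5 brighter of 18, namely Shmt2 (4.50-fold), Slc7a11 (3.66-fold), Asns (3.55-fold), Psat1 (2.71-fold) and Mthfd2 (2.30-fold), although the median of that list was 0.037. In the interferon list 1 of 6 genes was brighter (Usp18, 8.31-fold). In the unfolded protein list 3 of 16 were brighter, Dnajb9 (7.66-fold), Pdia4 (2.19-fold) and Edem1 (2.11-fold), and the log2 difference of 1.13 for Pdia4 became 0.40 as a mean over its 2 probe sets. Of 17 hypoxia and glycolysis genes, Egln3 (3.70-fold), Pfkl (2.66-fold), Ero1a (2.65-fold) and Ldha (2.07-fold) were brighter and Adm (3.22-fold) and Pfkfb3 (2.44-fold) dimmer. In the p53 list Ei24 (4.26-fold), Ccng1 (2.14-fold) and Phlda3 (2.09-fold) were brighter, in the neural crest list Dlx1 (7.55-fold), Twist1 (2.56-fold) and Dlx2 (2.28-fold), in the heat shock list Dnaja1, Hsph1 (2.16-fold) and Hsp90aa1 (2.06-fold), and in the keratinocyte list the desmosome gene Dsg3 (7.39-fold). None of the 5 bright Schwann cell genes differed by 2-fold. Of 10 genes listed as stable references, Tfrc (4.55-fold) and Hprt (4.06-fold) were brighter and Polr2a (2.34-fold) was dimmer, and their median of 0.61 (percentile 80.0) was close in size to that of the S-phase list. In all, 2079 of 11933 bright genes were at least 2-fold brighter on the array labelled high doxycycline and 1008 were dimmer. Among genes above percentile 75 of brightness the S-phase, immediate early and antigen presentation medians were 0.97, -0.46 and -0.33, at percentiles 94.3, 2.59 and 2.57, inside the range of random lists. The probe sets of a gene disagreed by at least 1 on the log2 scale for 20.0% of 679 genes, against 0.768% of 651 genes between the arrays labelled tumor and high doxycycline, where differences in general were smaller (SD over all probe sets 0.28 against 0.79).

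**Figure D2:**
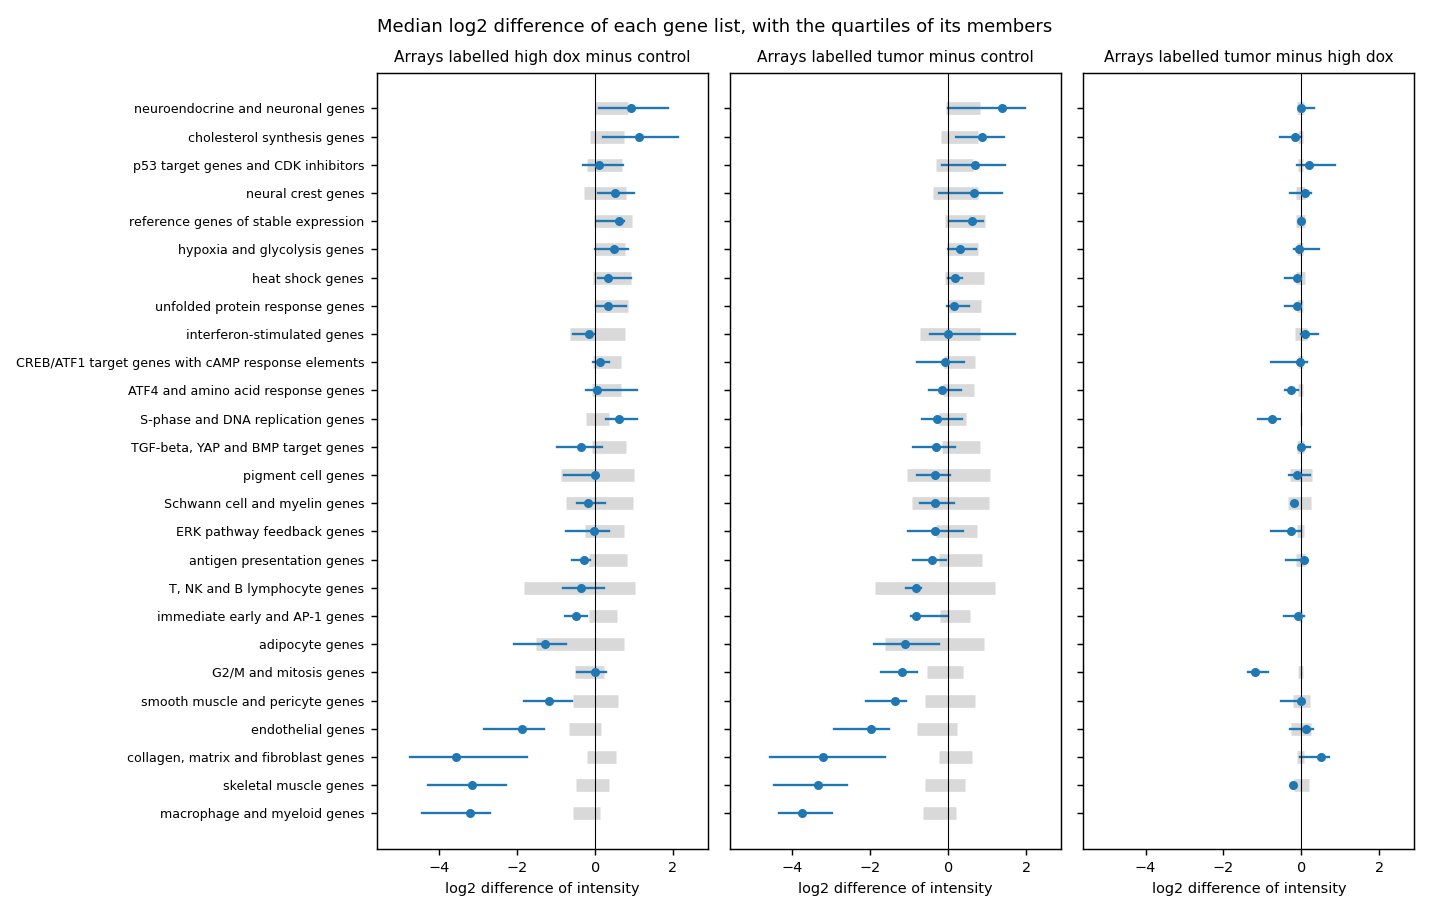
Median log2 difference of each gene list (dots, x axis) for the 3 pairs of arrays, with the quartiles of its bright members (blue lines); grey bars span percentiles 2.5 to 97.5 of 10000 random lists of matched brightness, and lists with fewer than 3 bright members have no dot. The collagen list lies at -3.58, -3.21 and 0.51 from left to right, and the G2/M list at -0.015, -1.18 and -1.18.

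The second comparison set the array labelled tumor against the array labelled control. By these labels it would ask how a tumor grown under doxycycline differs from cells kept without it, which is left unanswered in the same way. Fos was 3.68-fold dimmer on the array labelled tumor (302) than on the array labelled control (1114). The orphan receptor gene Nr4a3, a target of CREB-family factors, was 9.70-fold dimmer (325 against 3160), and the ERK phosphatase gene Dusp6 was 7.54-fold dimmer (455 against 3435). Brightest relative to the array labelled control were Ncam2 (52.5-fold), the synaptic adhesion gene Lrrc4c (29.2-fold), Nell2 (27.8-fold), Pcdhb9 (23.9-fold), the cell adhesion gene Alcam (23.8-fold), Olfm3 (21.8-fold) and the phospholamban gene Pln (20.4-fold), and Scoc with the same disagreement between its probe sets (4.65 against a mean of 2.28). Dimmest were Ccl8 (85.4-fold), Wfdc17 (78.8-fold), C1qb (60.4-fold), Lyz2 (59.8-fold), Saa3 (56.7-fold), Cd74 (48.5-fold), Ifi205 (44.1-fold) and the mannose receptor gene Mrc1 (42.2-fold). Atf1 was 1.27-fold and Ewsr1 1.02-fold dimmer on the array labelled tumor.

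Tissue genes were again dimmer, here on the array whose label names tissue. The macrophage list had a median log2 difference of -3.75 with 18 of 18 genes dimmer, the skeletal muscle list -3.35 (14 of 15), the collagen list -3.21 (16 of 18) and the endothelial list -1.98 (14 of 16), each below every random list, and the smooth muscle list -1.37 (7 of 9, percentile 0.02). The fast myosin gene Myh4 was 31.6-fold dimmer, Col1a1 30.1-fold and the receptor gene Kdr of blood vessels 19.2-fold. Beside these, 10 of 14 G2/M genes were dimmer on the array labelled tumor (median -1.18, percentile 0.01), with Ccna2 (4.22-fold), Aurkb (4.04-fold), Plk1 (3.58-fold) and Mki67 (3.50-fold) the largest. The S-phase list had Rrm2 (3.90-fold) and Uhrf1 (3.13-fold) dimmer and Rfc4 (5.80-fold) and Prim1 (2.87-fold) brighter, with a median of -0.29 over 25 genes (percentile 1.69). In the immediate early list Ier3 (3.87-fold), Fos, Egr1 (2.88-fold) and Btg2 (2.51-fold) were dimmer and none of the 21 was brighter by 2-fold (median -0.83, below every random list). The ERK feedback list (median -0.35, percentile 1.89) had Dusp6, Etv4 (3.54-fold) and Spry1 (2.30-fold) dimmer, and Etv1 (5.32-fold) and Phlda1 (2.04-fold) brighter. Of 20 CREB/ATF1 target genes, Scg2, Pcsk1 (3.16-fold) and Rgs2 (2.29-fold) were brighter and Nr4a3, Per1 (3.98-fold) and Fos dimmer. Their median of -0.084 (percentile 3.33) became 0.10 when the arrays were shifted to a common median, and over genes with a single probe set it was -0.31, at percentile 0.43. In the TGF-beta, YAP and BMP list (median -0.32, percentile 0.65) Ccn1 (3.45-fold), Ltbp2 (3.26-fold) and Ccn2 (2.96-fold) were dimmer and Id2 (4.47-fold) and Id1 (2.10-fold) brighter. The antigen presentation list had a median of -0.41 (percentile 0.57), with Cd74 and H2-Ab1 (2.36-fold) dimmer. In the amino acid response list Shmt2 (3.35-fold), Asns (3.16-fold) and Slc7a11 (2.08-fold) were brighter and Cebpb (2.48-fold) was dimmer. Its median of -0.17 (percentile 1.79) became 0.017 under a common median, and it lay inside the range of random lists under quantile normalization (-0.25, percentile 4.86).

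Neuronal genes were brighter on the array labelled tumor than on the array labelled control, 8 of 15 by at least 2-fold (median 1.39, percentile 99.98), with Scg2 at 15.0-fold, Uchl1 at 6.77-fold and Snap25 at 5.26-fold. In the list for cholesterol synthesis 7 of 15 were brighter (median 0.86, percentile 98.8), with Idi1 at 4.38-fold and Msmo1 at 4.13-fold. In the p53 and CDK inhibitor list 5 of 16 were brighter (median 0.70, percentile 98.5), namely Ei24 (4.46-fold), the cell cycle inhibitor genes Cdkn2b (3.15-fold) and Cdkn2a (2.96-fold), Phlda3 (2.84-fold) and Ccng1 (2.71-fold). In the neural crest list Dlx1 (8.58-fold), the nerve growth factor receptor gene Ngfr (6.64-fold), Twist1 (3.15-fold), Dlx2 (2.42-fold) and Snai2 (intensity 371 against 182) were brighter, and none of the 12 was dimmer by 2-fold. The interferon list had Usp18 (11.7-fold) and Ifit3 (10.5-fold) brighter and Irf7 (2.10-fold) dimmer. The 10 reference genes had a median of 0.61 (percentile 81.8), with Tfrc (6.89-fold) and Hprt (4.05-fold) brighter and Polr2a (2.29-fold) dimmer. In all, 2225 of 12010 bright genes were at least 2-fold brighter on the array labelled tumor and 1222 were dimmer. Among genes above percentile 75 of brightness, the medians of the G2/M list (-1.84, 3 genes left), the ERK list (-0.13), the cholesterol list (1.13), the S-phase list (-0.27) and the amino acid response list (-0.066) lay inside the range of random lists, at percentiles 12.8, 8.20, 96.3, 17.0 and 4.43. The p53 list lay inside it under quantile normalization (0.52, percentile 97.4), and the cholesterol list over genes with a single probe set (0.77, percentile 97.2).

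Both comparisons use the array labelled control. Of 11860 genes bright in both, 1811 were brighter than on that array in both comparisons, of 2055 and 2155, where independent lists would share 373.4. Dimmer in both were 903, of 1008 and 1222, where independent lists would share 103.86. Simulated arrays with no change against the same control shared 3.76 and 4 genes with the noise of the arrays labelled high doxycycline and tumor, and 491.8 and 570.9 where the control also carried the disagreement between probe sets of a gene, a setting chosen after seeing the data. Only Prl7b1, Tslp, Ucp1 and Entpd3 went in opposite directions by at least 2-fold, all 4 brighter on the array labelled high doxycycline and dimmer on the array labelled tumor. The correlation of the differences across genes was 0.946 against 0.511 and 0.865 in these simulations, and the covariance 1.06 against 0.070 and 0.42, a difference of 0.990 and 0.642. Neither simulation holds an error that all probe sets of a gene share, and part of the overlap may come from the shared array, which could not be split.

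**Figure D3:**
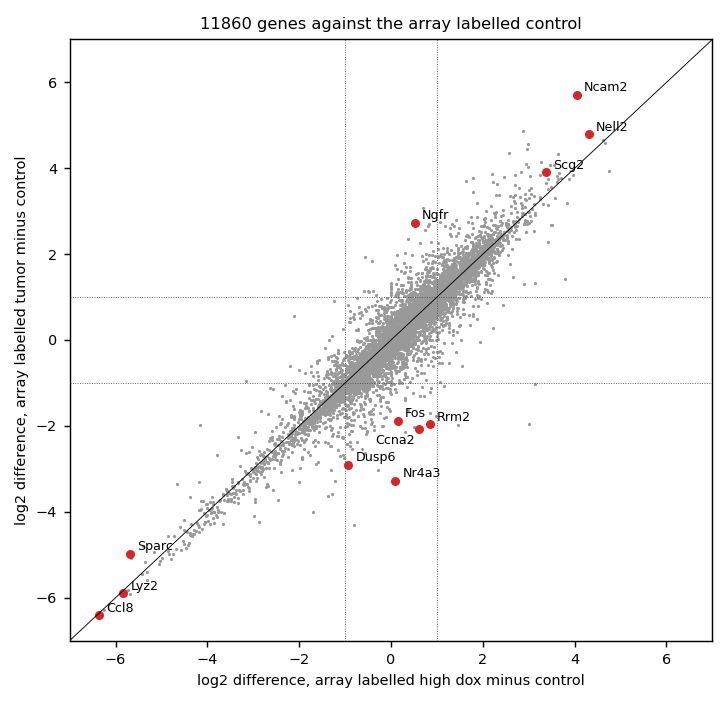
Log2 difference of 11860 genes from the array labelled control, for the array labelled high doxycycline (x axis) and the array labelled tumor (y axis); dotted lines mark 2-fold, the solid line is equality, and named genes are red. Most genes lie along the line, while Fos (0.15 and -1.88), Nr4a3 (0.09 and -3.28) and Dusp6 (-0.94 and -2.91) lie below it.

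The third comparison set the tumor against the culture with doxycycline, 2 samples that were both exposed to the drug according to the labels. These arrays differed least, with 177 of 11212 genes at least 2-fold brighter on the array labelled tumor and 217 dimmer. Fos was 4.07-fold dimmer on the array labelled tumor (302 against 1234), Nr4a3 10.3-fold (325 against 3357) and Dusp6 3.94-fold (455 against 1794). Also dimmer were Cyp3a44 (43.4-fold), the prolactin family gene Prl7b1 (30.8-fold), the uncoupling protein gene Ucp1 (17.8-fold), the cytokine receptor gene Csf2rb2 (11.2-fold), the cytokine gene Tslp (10.8-fold), the peptide hormone gene Apela (7.05-fold) and the ribonucleotide reductase gene Rrm2 (6.98-fold). Brighter were the small leucine-rich proteoglycan genes Ogn (8.12-fold) and Aspn (6.35-fold), the interferon-stimulated Ifit3 (6.81-fold), the water channel gene Aqp8 (6.45-fold), Inmt (5.62-fold), Trappc3l (5.23-fold), Fmo1 (4.83-fold) and B3galt2 (4.65-fold). Atf1 was 1.14-fold and Ewsr1 1.02-fold dimmer.

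Cell cycle genes were dimmer on the array labelled tumor as a group. In the G2/M list 10 of 15 genes were at least 2-fold dimmer and none brighter (median -1.18), with Ccna2 (6.40-fold), Bub1 (4.39-fold), the proliferation marker Mki67 (3.14-fold) and Plk1 (2.63-fold) the largest. In the S-phase list 7 of 26 were dimmer (median -0.75), including Rrm2, Uhrf1 (3.09-fold), Chaf1b (2.66-fold) and Mcm5 (2.47-fold). Both medians lay below every random list. In the p53 and CDK inhibitor list Cdkn2b (2.88-fold), Trp53inp1 (2.48-fold) and Eda2r (2.12-fold) were brighter (median 0.20, percentile 99.94, which became 0.00 at percentile 64.5 with no brightness filter).

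CREB/ATF1 target genes went both ways. Nr4a3, Fos and Crem (2.26-fold) were dimmer on the array labelled tumor, the G-protein regulator gene Rgs2 (2.06-fold) was brighter, and the median over 18 genes was -0.024 (percentile 15.7). That median turned positive under a common median (0.020) and under quantile normalization (0.0085). It lay below the range of random lists among genes above percentile 75 of brightness (-0.18, percentile 0.50), as a mean over all probe sets of a gene (-0.10, percentile 1.45) and over genes with a single probe set (-0.21, percentile 0.13). Of the immediate early genes Fos, Ier3 (2.88-fold) and Maff (2.33-fold) were dimmer and Jun (3.31-fold) was brighter, and the median of -0.092 had percentile 0.93. In the ERK feedback list Dusp6 was dimmer and Etv1 (2.14-fold) brighter (median -0.27, percentile 0.13). The amino acid response list had a median of -0.25, below every random list, with Psat1 (2.37-fold) the only gene past 2-fold. Its random lists spanned -0.075 to 0.030 here, against -0.090 to 0.66 for high doxycycline minus control. In this pair, where many values are exactly equal, a small shift can therefore reach an extreme percentile. The cholesterol list had -0.16 (percentile 0.32) with no gene past 2-fold. Ngfr (4.65-fold) and Snai2 (2.18-fold) were brighter in the neural crest list, whose median of 0.089 (percentile 97.8) became -0.016 (percentile 21.8) with no brightness filter. The unfolded protein list had a median of -0.11 (percentile 2.46) with no gene past 2-fold, and at percentile 2.64 it lay inside the range of random lists over genes with a single probe set. The 5 bright skeletal muscle genes had -0.21 (percentile 2.25), and -0.16 inside that range under quantile normalization (percentile 2.86). The median of 13 collagen and matrix genes was 0.51, above every random list, with Col6a1 (2.14-fold) brighter by 2-fold, and with no brightness filter it was 0.15 over 19 genes (percentile 99.98). Of the macrophage list 2 genes were bright on either array, and 1 of them, Cd14, was 5.75-fold dimmer on the array labelled tumor. The 10 reference genes had a median of 0.00 and none differed by 2-fold. Among genes above percentile 75 of brightness, the ERK and immediate early medians moved to 0.00, at percentiles 52.7 and 54.9, and the neural crest median was 0.18, at percentile 92.6, all inside the range of random lists.

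**Figure D4:**
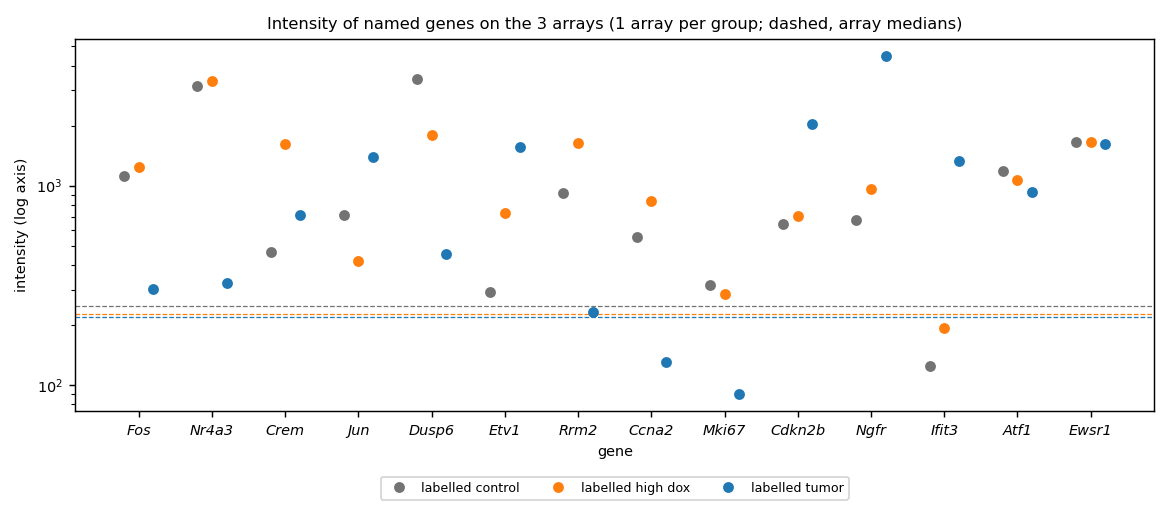
Intensity (y axis, log scale) of 14 genes named in the text (x axis) on the 3 arrays, 1 dot per array, with the median intensity of each array dashed. Fos is at 1114 on the array labelled control, 1234 on high doxycycline and 302 on tumor, while Jun is at 710, 421 and 1396.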

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

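All tests of explanations in this part were chosen after the results had been seen. Of 72 measured genes of the macrophage, endothelial, skeletal muscle and collagen lists, 67 lay above the median of the array labelled control, and 62 of these were at least 2-fold brighter there than on the array labelled high doxycycline (median log2 difference 2.97, quartiles 1.71 and 4.19, and a median of 3.07 after quantile normalization). Admixed tissue in the control culture and expression of the fusion in both exposed samples both stay open. Of the 67 genes, 34 were blood and vessel genes, which a resected tumor would keep. Their difference of tumor from high doxycycline had a median of -0.14 and an upper quartile of -0.069. Admixture in the control alone would not account for their dim values on tumor. This difference restates those dim values and leaves out the array labelled control, so it cannot decide whether tissue was admixed there. It also takes the tumor label as given, and so cannot decide on the fusion either. The 18 collagen and matrix genes had a median of 0.18 and an upper quartile of 0.64 for the same difference. The matrix genes Ogn (8.12-fold) and Aspn (6.35-fold) were brighter on tumor. The 15 muscle genes, which a tumor need not hold, were not used. Exchanged labels of the arrays labelled control and tumor are a candidate explanation that the tissue genes prompted and cannot test. The Y-linked genes Eif2s3y, Uty and Kdm5d differed by at most 0.15 between high doxycycline and tumor. They were 2.55, 2.38 and 1.09 brighter on high doxycycline than on control. A tumor and a culture of male origin could match in this way as well. Because these arrays correlated at 0.991 over all probe sets, most genes would match, so this match does not bear on the labels. A shared male origin leaves the lower Y-linked values on control unexplained, and those values do not decide whether labels were exchanged. Xist, expressed from the inactive X chromosome of females, lay below the median of every array (6.01, 6.01 and 5.92). These data do not separate an exchange at labelling from one in the deposited table or from 2 unrelated errors, and although the labels give both cultures the same number and the tumor another, what these numbers stand for is not given.

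Fos, Nr4a3, Dusp6 and cell cycle genes were brighter on the array labelled high doxycycline than on the array labelled tumor, with Fos at 4.07-fold and the mitosis list at a median of -1.18 for tumor minus high doxycycline. For the mitosis list, a different scale of the deposited values is argued against as the cause. The medians of these arrays differed by only 0.04, and the mitosis median was -1.08 after quantile normalization. With medians this close, quantile normalization could change little, and it does not test the authors' own normalization. Induction of the fusion in culture stays open: Atf1 differed by -0.19, and mouse probe sets need not detect a fusion transcript. If the labels of control and tumor were exchanged, this pair would be the cultures with and without doxycycline, and the brighter Fos with the drug may then be a response to it. The arrays as labelled confound the dose and time of doxycycline with growth in an animal, so that this cannot be told apart from a difference between tumor and culture.

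Probe sets without a single gene symbol, which enter no comparison, also differed from the array labelled control. Of 2604 such probe sets with sufficient brightness, 269 were at least 2-fold brighter on the array labelled high doxycycline and 293 were dimmer. Between the arrays labelled tumor and control, 254 of 2624 were at least 2-fold brighter on tumor and 374 dimmer.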

How the results depend on the processing

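With 1 array per group no array could be left out, so no comparison survives without the arrays whose contents go against their labels. No paired analysis was possible because each group has 1 array. Over all alternatives, 59 counts of genes stayed within 1.5 times their value and 5 did not, all 8 correlations across genes moved by less than 0.05, and of the list medians 538 moved by less than their bootstrap spread and 45 by more. Among these, 16 values of lists inside the range of random lists changed sign, and so did 2 further values of lists outside it. Of single-gene differences 1672 moved little and 180 moved, and 5 changed sign, all of Ewsr1 and Fos at under 2-fold. The brightness filter limits what dim genes can show. The share of brighter genes among those past 2-fold was 67.3%, 64.5% and 44.9% in the 3 comparisons, against 74.7%, 74.1% and 49.0% after a common median and 59.3%, 58.7% and 47.2% after quantile normalization. The cause was not tested for any of the following values except where fewer genes enter by construction. Above percentile 75 of brightness, where fewer genes enter, the dimmer genes were 569 for high doxycycline and 691 for tumor against control (501 shared), and for tumor against high doxycycline 103 were brighter and 144 dimmer.

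For high doxycycline minus control, a common median gave -0.35 for immediate early and 0.26 for CREB/ATF1 genes, and quantile normalization -0.71 and -0.16. Percentile 75 gave 0.97 for S-phase, -0.45 for G2/M, 0.95 for p53, -0.74 for TGF-beta, -1.85 for smooth muscle, -3.95 for macrophage, -3.20 for endothelial and -3.76 for skeletal muscle genes. No filter gave 0.00 for neural crest and -0.62 for smooth muscle genes, pseudocount 64 gave -2.76 for macrophage genes, and genes with a single probe set gave 0.21 for hypoxia. For tumor minus control, a common median gave -0.64 for immediate early genes, 0.33 for unfolded protein, 0.36 for heat shock and 0.017 for amino acid response genes, the last with its sign changed from -0.17. Quantile normalization gave -0.079 for unfolded protein and -0.030 for heat shock genes. Percentile 75 gave 1.66 for neural crest, -1.84 for G2/M, 1.47 for p53, -0.71 for antigen presentation, -2.59 for smooth muscle, -4.17 for macrophage, -3.38 for endothelial and -3.92 for skeletal muscle genes. No filter gave -0.060 for neural crest and -0.32 for lymphocyte genes, pseudocount 64 gave -0.92 for G2/M and -3.12 for macrophage genes, and single probe sets gave -0.78 for ERK feedback. For tumor minus high doxycycline, no filter gave -0.016 for neural crest genes, with the sign changed from 0.089, -0.083 for Schwann cell, -0.89 for G2/M and 0.15 for collagen genes. Percentile 75 gave -1.0 for S-phase, -0.46 for antigen presentation and -0.41 for cholesterol genes, pseudocount 64 gave -0.64 for S-phase and -0.94 for G2/M, single probe sets gave -0.28 for heat shock, and reference genes had 0.044 after a common median and 0.030 after quantile normalization.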

Other observations

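The genes of this part were chosen after their values were seen, and the tests of explanations as well. In the protocadherin beta cluster, whose members are expressed in different combinations in single neurons, 12 of 22 genes were at least 2-fold brighter on the array labelled high doxycycline than on the array labelled control, led by Pcdhb9 (4.67 on the log2 scale), Pcdhb4 (3.56) and Pcdhb2 (3.32). Between the arrays labelled tumor and high doxycycline none of the 22 differed by 2-fold, and the largest difference was 0.27 in size. Across these 22 genes the log2 values of the latter pair correlated at 0.998, and those of high doxycycline and control at -0.026. On the array labelled control only Pcdhb15 (8.68) lay above the array median of 7.97, and Pcdhb16 came next (7.88). The value of -0.026 therefore rests mostly on dim values and does not show another combination of these genes on that array. The counts of 12 and 0 were the same under a common median and under quantile normalization. Of 37 Hox genes, which pattern the body axis, Hoxa10 (2.58), Hoxa9 (2.08), Hoxa6 (1.46) and Hoxa13 (1.29) were brighter on the array labelled high doxycycline than on the array labelled control, and Hoxc8 (-2.18) and Hoxd8 (-1.48) were dimmer. Neither family was filtered by brightness, and Hoxd8 lay just below the filter (7.95 on control against an array median of 7.97). The array labelled tumor showed the same directions for these 6 genes, with Hoxa10 at 3.35 and Hoxc8 at -2.26, and none of the 37 differed by 2-fold from high doxycycline (largest difference 0.92, Hoxa9).

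Genes of the vacuolar proton pump were brighter as a group on both other arrays than on the array labelled control. All 15 bright subunit genes lay above 0 for high doxycycline minus control (median 1.20, percentile 99.94, highest Atp6v1d at 2.37), 8 of them by at least 2-fold, and the median was 1.26 for tumor minus control. Under quantile normalization these medians were 0.93 and 1.03, and with no brightness filter they were 0.73 and 0.89 over 21 genes, of which Atp6v0d2 was dimmer (-1.97 and -2.14). Mitochondrial ribosomal protein genes had a median of 0.61 for high doxycycline minus control, with 24 of 77 brighter by 2-fold and 2 dimmer, Mrpl52 (-1.55) and Mrps16 (-1.03). Under quantile normalization the median was 0.33, with 19 brighter. As deposited, the family lay at percentile 99.83 of random lists, but the 10 reference genes had a median of 0.61 as well. Of all 11933 bright genes, 2079 were at least 2-fold brighter in this pair. Cytosolic ribosomal protein genes had a median of -0.17 with 10 of 49 above 0 and 5 at least 2-fold dimmer. The median was -0.027 with 2 dimmer after a common median, and -0.30 with 9 dimmer under quantile normalization.

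Subunits that work in 1 complex scattered widely in comparisons with the array labelled control. The SD over 37 proteasome subunit genes was 0.82 for high doxycycline minus control, from -0.83 (Psmb10) to 2.33 (Psmd14), against 0.14 for tumor minus high doxycycline. Over all probe sets, dim ones included, the SD was 0.79 and 0.28 for these pairs. The subunit genes had passed the brightness filter and the probe sets had not, so these SDs do not show whether subunits scattered more or less than comparable genes. The proteasome had the widest scatter of the complexes examined. For high doxycycline minus control, the SDs of the others ran from 0.45 (cytosolic ribosomal proteins) to 0.74 (mitochondrial ribosomal proteins). A probe-level difference of the array labelled control stays open: the median disagreement between probe sets of a gene, divided by the SD of all differences, was 0.39 for high doxycycline minus control and 0.24 for tumor minus high doxycycline. A tissue sample set against a culture stays open as well: the SD over cytosolic ribosomal protein genes was 0.45, and no size was set in advance for such a pair. The 2 explanations cannot be told apart here, because both would concern the same 1 array.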
